A study of Mus musculus with 4 samples.

How the data were processed

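RNA sequencing libraries came from RAW264.7 cells, a mouse macrophage cell line. Per the labels, attached cells were cultured for a further 48 h with the test material. RNA was extracted with TaKaRa RNAiso Plus, and libraries were made with the CORALL RNA-seq V2 kit. Sample titles separated 2 libraries named Gel from 2 libraries named CuNZ@Gel, and the groups were taken from these titles. The treatment text names only CuNZ@Gel, so what the Gel cells received was read from the titles alone. The labels do not spell out CuNZ. Nothing in them says that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

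The deposited files held 1 log2 value per gene symbol and library for 40213 symbols, written to 3 decimals. Per the submitters' processing notes, fastp, STAR, Salmon and GATK were used with the mouse genome build GRCm39. Their versions, roles and settings, the annotation, the use of strand, the treatment of molecular identifiers and the normalization method are not given in the sources used here. From the values themselves, each deposited log2 value was log2(x + 1), where x was CPM divided by 1 factor per library. Such values are called scaled CPM. They were not divided by gene length, because the smallest step above 0 was the same for all genes of a library. Between 92.8% and 93.5% of the values of at most 1 were whole multiples of that step within 0.02 reads, and this step gave the reads behind each value. The library totals so recovered were 14733000 and 13717000 for Gel replicates 1 and 2, and 14880000 and 14736000 for CuNZ@Gel replicates 1 and 2, rounded. The further factors were 0.937, 0.936, 1.07 and 1.07 in the same order. A trimmed mean of M-values calculation on the recovered reads gave 0.936, 0.935, 1.07 and 1.07. The value of 3 reads, the limit that a count of 0 allows at 95% confidence, was 0.217, 0.234, 0.189 and 0.190 scaled CPM. Such limits and the intervals printed for ratios cover counting error only.

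The planned test assumed counts. Because the files held log2 values, the test written for normalized values before the data were examined was used in its place. Genes with at least 1 scaled CPM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean and with the deposited log2 values, whose pseudocount is 1. The model held the group alone, fitted to all 4 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are therefore on the log2(scaled CPM + 1) scale, which understates the change of genes at low levels. A change given without the word fold is a log2 change. Levels are means ± SD of scaled CPM over the 2 libraries of a group.

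Before the data were examined, 31 gene lists were fixed from the cell line, the treatment and general knowledge of macrophages, among them markers of other cell types. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01. That left 28 lists, and their p-values were adjusted together. Camera was also run with an estimated correlation, for which it has only 2 residual degrees of freedom, and fry was run as a further alternative. Members were counted by their gene test adjusted over all tested genes and adjusted over the list alone.

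The rule for the genes named was also fixed beforehand. It took the 10 raised and the 10 lowered genes with the smallest p among those past the threshold, with a mean of at least 5 scaled CPM in the higher group and with no overlap between the groups. From each list it took up to 4 members with the smallest p past the threshold adjusted over the list alone, and it added 10 anchor genes. The rule gave 127 genes, of which 2 are not reported here. Apart from these, where fewer than 4 members of a list are named, they are those with the smallest p. Genes outside the rule are said to have been chosen after their values were seen.

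Alternatives were other scalings (relative log expression and upper-quartile factors, and total reads only), limma-voom on the recovered reads, no filter, a filter at 5 scaled CPM, a pseudocount of 0.1, a test against a minimum fold of 1.5, removal of mitochondrial and ribosomal RNA genes, each library left out in turn, and the replicate number as a block. Total reads only, a crossed block and a correction of each library for transcript length and GC content were added after the data were seen. Length and GC content came from the longest transcript of each gene in GENCODE vM21, whose build differs from that of the files, so that only these properties and no coordinates were used. Matching by symbol or gene identifier gave a transcript for 95.7% of the tested genes.

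The procedure was tested on data simulated for this comparison from the real levels and depths, with 11486 genes tested. Of genes changed by 1.25-fold, 42.0% were called, against 77.6% at 1.5-fold, 95.9% at 2-fold and 100% at 4-fold. Unchanged genes made up 6.02% of the calls. In the simulation 11288 of the 11486 genes were unchanged and all genes shared 1 dispersion, whereas 67.1% of the real tested genes were called. The adjusted threshold depends on the share of changed genes, so these rates do not carry over to the real calls.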

Results

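The series measured gene expression by RNA sequencing in RAW264.7 mouse macrophages after 48 h with material labelled Gel (n = 2 libraries) or CuNZ@Gel (n = 2 libraries), read here as the hydrogel without and with CuNZ. The series title places the material in work on a nanozyme hydrogel for diabetic wounds and on epigenetic control of inflammation. The single comparison of the design asks how CuNZ in the gel alters the macrophage transcriptome. Recovered library totals ranged from 13717000 to 14880000 reads. Within a group, libraries correlated across genes with a Pearson r of 0.995, and genes are not independent replicates. Between groups this r ranged from 0.930 to 0.938. The chi-square statistic per gene was 3.84 for the Gel pair and 4.59 for the CuNZ@Gel pair, against 136 to 166 for pairs from different groups, so that no pair agreed within sampling noise. The share of reads on some RNA classes differed between the groups. Gm26917, a ribosomal RNA-like transcript, took 11.8% ± 0.0777 of the reads in Gel and 7.14% ± 0.0561 in CuNZ@Gel (SD, n = 2). Mitochondrially encoded protein genes took 8.0% ± 0.601 and 9.64% ± 0.289, and cytosolic ribosomal protein genes took 10.6% ± 0.30 and 5.51% ± 0.350.

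Hmox1, the inducible heme oxygenase, rose from 83.3 ± 4.79 to 1172 ± 61.5 scaled CPM (SD, n = 2 per group), a 14.1-fold difference of the means. Cat, the peroxide-degrading catalase, rose 10.8-fold, and Cd36, a scavenger receptor for oxidized lipoproteins, rose 27.0-fold. Nupr1, a stress-induced chromatin protein, fell from 170 ± 5.02 to 14.5 ± 1.32 scaled CPM, and Ddit3, the transcription factor CHOP, fell from 204 ± 8.64 to 26.8 ± 1.97. Of 11588 genes tested with limma, 7770 (67.1%) changed at an adjusted p under 0.05, of which 3737 were raised and 4033 lowered. Raised genes made up 48.1% of the calls, and 63.7% when libraries were scaled by total reads only, which moved the median log2 change of all genes by 0.18. A change of at least 2-fold on the log2(scaled CPM + 1) scale was seen for 818 raised and 709 lowered genes, and of at least 4-fold for 147 and 64. The groups did not overlap for 83.2% of the tested genes, where chance gives 33.3%. With a test against a minimum fold of 1.5, 1955 genes were called.

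The 10 raised genes with the smallest p also held Acod1, which makes the immunometabolite itaconate (from 7.51 ± 0.275 to 184 ± 3.35 scaled CPM), and Clec4d, a C-type lectin receptor (from 51.3 ± 4.78 to 482 ± 13). Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, rose 13.6-fold. Prdx1, a peroxiredoxin, rose 5.25-fold from the high level of 475 ± 5.83 scaled CPM. Ccng1, the p53 target cyclin G1, rose 7.34-fold, and Spink5, a serine protease inhibitor, 5.45-fold. Serpinb9b, of the serpin family, had 3 reads in the Gel libraries together and 2730 in the CuNZ@Gel libraries, a ratio of 756 with a 95% exact counting interval from 262 to 3720. Among the 10 lowered genes, Trib3, a pseudokinase of the stress response, had a log2 change of -3.43. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, and Asns, which makes asparagine, fell as well (-3.07 and -2.21). Shmt2 and Mthfd2, enzymes of mitochondrial one-carbon metabolism, fell (-2.12 and -2.09), as did Slc7a5, a transporter of large neutral amino acids (-2.33). H2ac23 and H1f0, which encode an H2A histone and a linker histone, changed by -3.24 and -2.04. The limma adjusted p of these 20 genes lay between 1.01e-20 and 1.38e-16, and both CuNZ@Gel libraries lay on the same side of both Gel libraries for each. H2ac23 has near-identical paralogs whose reads may have been split in counting, so its level is uncertain.

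**Figure D1:**
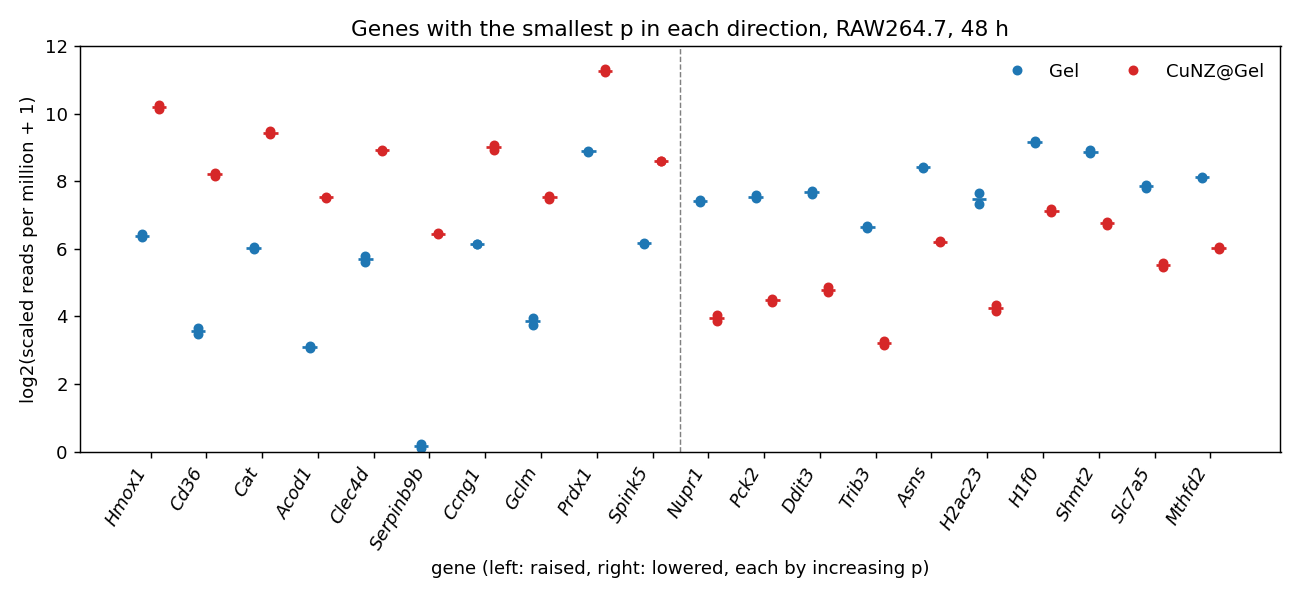
Each point is 1 library's log2(scaled CPM + 1) for the 10 raised genes (left of the dashed line) and the 10 lowered genes (right of it) with the smallest p, in Gel (blue, n = 2) and CuNZ@Gel (red, n = 2), and each short line is a group mean. The groups do not overlap for any of these 20 genes, and the log2 changes run from -3.47 for Nupr1 to 6.29 for Serpinb9b.

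Antioxidant genes under the transcription factor NRF2 rose in CuNZ@Gel: 22 of 24 tested members were raised and none was lowered. The median log2 change was 1.43. Hmox1, Cat, Gclm and Prdx1 had the smallest p, with log2 changes of 3.80, 3.41, 3.67 and 2.39. Osgin1 and Txn1, at 0.18 and 0.08, did not pass the test and are named because they were the exceptions. Genes of iron handling and ferroptosis were raised in 14 of 18 cases and lowered in 2, with a median log2 change of 0.70. Slc11a1, an iron and manganese transporter of the phagosome, rose from 36.1 ± 0.182 to 234 ± 1.61 scaled CPM, and Slc40a1, the iron exporter ferroportin, from 7.07 ± 0.676 to 86.1 ± 3.93. Alox5, the 5-lipoxygenase, rose 4.57-fold. The lowered members, named after their values were seen, were Chac1, which degrades glutathione and belongs to the integrated stress response (-2.90), and Gpx4, which reduces lipid peroxides (-0.40). These lists share 4 tested genes, Hmox1, Slc7a11, Ftl1 and Fth1. Both passed camera, with adjusted p of 1.82e-13 and 2.56e-05. Neither passed with an estimated correlation, where no list did (adjusted p = 0.207 and 0.215 with an estimated correlation).

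The unfolded protein and integrated stress response list moved the other way: 23 of 29 tested members were lowered and 3 were raised, with a median log2 change of -1.24. Nupr1 (-3.47), Ddit3 (-2.88), Trib3 (-3.43) and Asns (-2.21) had the smallest p. The raised members, named after their values were seen, were Pdia4 (0.53), Hsp90b1 (0.43) and Dnajb9 (0.70), which encode chaperones of the endoplasmic reticulum. The list passed camera (adjusted p = 2.37e-10), but not with an estimated correlation, where no list passed (adjusted p = 0.207 with an estimated correlation).

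Sterol genes rose: 20 of 23 tested members of the cholesterol synthesis list were raised and 2 were lowered, with a median log2 change of 0.78. Hsd17b7, Sqle and Cyp51, enzymes of the sterol pathway, rose 6.11-fold, 2.48-fold and 2.42-fold. Camera gave an adjusted p of 7.57e-07 (adjusted p = 0.207 with an estimated correlation). Among genes of cholesterol efflux and its nuclear receptor LXR, 5 of 13 were raised and 2 lowered, and the list did not pass (adjusted p = 0.354). In it Apoe, the lipid carrier apolipoprotein E, fell from 38.1 ± 3.17 to 5.57 ± 0.241 scaled CPM. The desaturases Scd1 and Scd2 and the fatty acid synthase Fasn rose by 1.39, 0.92 and 0.88 on the log2 scale.

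Targets of p53 and apoptosis genes were raised in 15 of 23 cases and lowered in 6 (median log2 change 0.87). Mdm2, the ubiquitin ligase of p53, rose from 87.2 ± 2.59 to 521 ± 44.9 scaled CPM, and Cdkn1a, the cell cycle inhibitor p21, from 80.1 ± 3.46 to 357 ± 10.9. Ccng1 and Trp53inp1 rose 7.34-fold and 9.80-fold. Camera gave an adjusted p of 8.99e-04 (adjusted p = 0.258 with an estimated correlation). Cell cycle genes were lowered in 23 of 36 cases and raised in 7 (median -0.29), against 16 and 11 (median -0.10) with libraries scaled by total reads only. Ube2c, a mitotic ubiquitin-conjugating enzyme, fell (-1.28), as did the cyclins Ccna2 and Ccnb2 (-1.04 and -1.08). Mki67, the proliferation marker Ki-67, fell by 0.89. The list passed camera at an adjusted p of 0.0230 (adjusted p = 0.349 with an estimated correlation). Replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, were lowered in 26 of 29 cases and raised in 3 (median -1.50). The linker histone genes H1f3, H1f4 and H1f1 fell (-2.53, -2.38 and -2.57), whereas H2bc4 rose by 2.23. Camera gave an adjusted p of 3.66e-06 (adjusted p = 0.207 with an estimated correlation). Without Gel replicate 2 this list no longer passed, with a median of -1.22 and an adjusted p of 0.0637. Reads of histone paralogs may have been split in counting. Non-histone RNAs that lack a poly(A) tail moved with this list: 7 of 7, a set chosen after the data were seen, were lowered.

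Nuclear genes of oxidative phosphorylation were lowered in 26 of 38 cases and raised in 4 (median -0.36), against 20 and 8 (median -0.17) with libraries scaled by total reads only. Uqcrq and Uqcrfs1, of respiratory complex III, fell (-1.19 and -0.77), as did Ndufb10 and Ndufv2, of complex I (-0.84 and -0.65). The list passed camera (adjusted p = 8.99e-04), but neither with an estimated correlation (adjusted p = 0.723 with an estimated correlation) nor with fry (adjusted p = 0.0623). After correction for transcript length and GC content its median was -0.06 (adjusted p = 0.601). Across the tested genes, which are not independent replicates, the log2 change correlated with log2 transcript length at a Pearson r of 0.306. Mitochondrially encoded transcripts were raised in 6 of 13 cases and lowered in 3 (adjusted p = 0.311), while their share of all reads was higher in CuNZ@Gel. ND4L, ND5 and ATP8 rose by 1.47, 0.98 and 0.80, and ND3 fell by 0.58. ND4L and ATP8 overlap neighbouring genes, so their values are uncertain. In the fits with 1 library left out, the median of this list was 0.07 to 0.16. Of the glycolysis and hypoxia list, 10 of 27 genes were raised and 8 lowered (median 0.03, adjusted p = 0.719), against 15 and 3 (median 0.21) with libraries scaled by total reads only. In it the hexokinase gene Hk1, the glucose transporter gene Slc2a1 and the pyruvate kinase gene Pkm rose by 0.86, 0.75 and 0.67, and Vegfa, an angiogenic growth factor, fell by 0.99.

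Metallothioneins, which bind copper and zinc, rose with CuNZ@Gel. Mt1 rose from 254 ± 17.7 to 733 ± 46.7 scaled CPM and Mt2 from 97.9 ± 5.09 to 274 ± 7.95. Slc39a10, a zinc importer, rose 2.43-fold and Atp7a, a copper-exporting ATPase, 1.82-fold. In the copper and metal list, 10 of 18 genes were raised and 5 lowered (median 0.27), against 10 and 1 (median 0.46) with libraries scaled by total reads only. Camera did not pass the list (adjusted p = 0.121). With any 1 of the 4 libraries left out its median was 0.25 to 0.27. The list passed camera after the length and GC correction (median 0.14, with 7 raised and 2 lowered, adjusted p = 0.0162). It also passed camera with the replicate number as a block (adjusted p = 0.0372) and passed fry (adjusted p = 0.00576). The cuproptosis and lipoylation list had 5 of 16 genes raised and 8 lowered (adjusted p = 0.513). In it the pyruvate dehydrogenase complex genes Dld, Pdha1 and Pdhb fell (-0.63, -0.69 and -0.57).

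Inflammatory genes moved in both directions. In the pro-inflammatory M1 list, 9 of 20 genes were raised and 4 lowered, with a median log2 change of 0.14. Acod1, with the smallest p and the largest change in this list, rose 24.4-fold. The chemokine genes Ccl3 and Ccl4 rose 1.97-fold and 2.44-fold, and Cd80, a costimulatory molecule, 3.23-fold. Tnf rose from 75.7 ± 1.77 to 110 ± 1.36 scaled CPM, a log2 change of 0.54. Il1b rose from 0.264 ± 0.0663 to 2.78 ± 0.551 scaled CPM, on 7 and 88 reads. Nos2, the inducible nitric oxide synthase, did not pass the test, at 1.96 ± 0.525 in Gel and 1.61 ± 0.395 in CuNZ@Gel (adjusted p = 0.454). Il6, Il10 and Arg1 were listed at 0 in all 4 libraries. The list did not pass camera (adjusted p = 0.0839). Its median was -0.02 without CuNZ@Gel replicate 2 and 0.03 without CuNZ@Gel replicate 1. Without Gel replicate 1 or 2 it was 0.17 or 0.12. The list passed camera with the filter at 5 scaled CPM (median 0.535, adjusted p = 0.0303) and after correction for transcript length and GC content (median 0.41, adjusted p = 0.0148). It also passed camera with the replicate number as a block (adjusted p = 0.00123) and passed fry (adjusted p = 0.00371). Of the alternative M2 list, 7 of 14 genes were raised and 5 lowered (median 0.59, adjusted p = 0.141). Its median was 0.10 without CuNZ@Gel replicate 2 and 0.25 without CuNZ@Gel replicate 1, and the list passed after the length and GC correction (median 0.66, adjusted p = 0.0249). The M2 list also passed camera with the block (adjusted p = 0.00276) and passed fry (adjusted p = 0.00273). Cd36 rose, as did Il1rn, the interleukin 1 receptor antagonist (3.98-fold), Msr1, a scavenger receptor (2.11-fold), and Mrc1, the mannose receptor (from 1.00 ± 0.534 to 4.96 ± 1.90 scaled CPM). Klf4, a transcription factor of alternative activation, fell from 44.1 ± 1.06 to 6.96 ± 0.682.

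Inflammasome genes were raised in 7 of 12 cases and lowered in 2 (median 0.19, adjusted p = 0.141). Nlrp3, Nlrc4, Casp1 and P2rx7, which encode sensors, the effector caspase and the ATP-gated receptor, rose by 1.53, 1.45, 1.42 and 1.14. The median of this list ranged from 0.14 to 0.20 with 1 library left out. The NF-kB and TLR signalling list had 8 of 25 genes raised and 8 lowered (adjusted p = 0.995). The kinase pathway genes Ikbkg and Map3k7 rose by 1.45 and 0.84, and Irak1 and Traf1 fell (-0.64 and -1.14). The interferon response list had 9 of 23 genes raised and 9 lowered (adjusted p = 0.761). Usp18, which restrains interferon signalling, fell (-1.31), as did the interferon-induced genes Bst2, Oas1a and Ifi44 (-1.26, -0.95 and -0.89). In the same list Rsad2, Ifit1, Ifit2 and Ifit3, named after their values were seen, rose by 1.59, 1.38, 1.14 and 1.42.

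Enzymes that write, read or remove chromatin marks, the subject of the series title, moved both ways, and none of their lists passed camera. DNA methylation enzymes were raised in 7 of 14 cases and lowered in 6 (median 0.14, adjusted p = 0.701), and fry passed the list as raised (adjusted p = 0.0205). After the length and GC correction 5 were raised and 5 lowered (median -0.003), and with 1 library left out the median was 0.04 to 0.13. Dnmt3l, a cofactor of de novo methylation, rose from 0.529 ± 0.132 to 8.03 ± 0.487 scaled CPM. Dnmt1, the maintenance methyltransferase, rose 1.43-fold and its partner family member Uhrf2 1.92-fold, while Mbd3, of a chromatin remodelling complex, fell by 0.55. Histone acetylation enzymes were raised in 6 of 27 cases and lowered in 10, or 9 adjusted over the list alone (median -0.01, adjusted p = 0.995). With libraries scaled by total reads only, 12 of these genes were raised and 5 lowered (median 0.17). The acetyltransferase genes Kat6b, Ep300 and Kat2b rose by 1.07, 0.63 and 0.92, and the deacetylase gene Hdac4 by 0.95. Histone methylation enzymes were raised in 21 of 38 cases, or 22 adjusted over the list alone, and lowered in 9 (median 0.26, adjusted p = 0.168). Setd7, Kmt2d and Setd1a, which encode lysine methyltransferases, rose by 1.15, 0.83 and 0.66, and the arginine methyltransferase gene Prmt5 fell by 0.67. After correction for transcript length and GC content, the histone methylation list had 8 genes raised and 17 lowered, and Kmt2d and Mbd3 no longer passed, at 0.08 and -0.12.

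Heat shock genes were raised in 7 of 18 cases and lowered in 6 (median 0.02, adjusted p = 0.792). After the length and GC correction 6 heat shock genes were raised and 10 lowered (median -0.16). Of these chaperone and co-chaperone genes, Hsp90aa1 and Hsph1 rose by 0.94 and 1.06, Dnajb4 rose by 1.05 and Fkbp4 fell by 0.74. In the lysosome and autophagy list, 11 of 30 genes were raised and 10 lowered (adjusted p = 0.839). Tfeb, the transcription factor of lysosome genes, fell from 39.0 ± 1.63 to 9.91 ± 0.444 scaled CPM. The proton pump subunit gene Atp6v1h and the cathepsin gene Ctsl rose by 0.98 and 0.73, and the hexosaminidase gene Hexa fell by 0.67.

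Wound-healing growth factors and matrix enzymes were raised in 9 of 16 cases and lowered in 4 (median 0.30, adjusted p = 0.15). Spp1, the matrix protein osteopontin, rose from 1404 ± 63.3 to 6275 ± 138 scaled CPM. The growth factor genes Vegfb and Pdgfa fell (-1.32 and -1.51). The median of this list ranged from 0.26 to 0.34 with 1 library left out. Phagocytosis and efferocytosis genes were raised in 9 of 20 cases, or 10 adjusted over the list alone, and lowered in 7 (adjusted p = 0.304). Cd36, with the smallest p in this list, rose by 4.64. The Fc receptor gene Fcgr4 and the lipoprotein receptor gene Scarb1 rose by 1.97 and 0.88, and Gas6, a bridging ligand for apoptotic cells, fell by 1.16. The median of the phagocytosis list was 0.25 with all 4 libraries and ranged from 0.22 to 0.37 with 1 library left out.

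Macrophage identity genes were raised in 9 of 19 cases and lowered in 5 (adjusted p = 0.143). Itgam, the integrin CD11b, rose from 84.0 ± 3.66 to 314 ± 11.9 scaled CPM. Lyz2, the macrophage lysozyme, and Adgre1, the marker F4/80, rose by 0.94 and 0.83, and Tyrobp, a signalling adaptor, fell by 0.82. The median of the identity list ranged from 0.08 to 0.25 with 1 library left out. The list passed camera after the length and GC correction (median 0.28, against 0.13 without it, adjusted p = 0.0162). Osteoclast markers, included because this line can form osteoclasts, were raised in 6 of 10 cases and lowered in 2 (adjusted p = 0.277). Dcstamp and Ocstamp, needed for cell fusion, rose by 2.25 and 1.44, and Tcirg1 and Atp6v0d2, proton pump subunits, changed by 0.33 and -0.72. Ocstamp rose from 0.256 ± 0.253 to 2.37 ± 0.235 scaled CPM, on 7 and 75 reads. Dendritic cell markers had 1 of 6 genes raised and 4 lowered, or 5 adjusted over the list alone (adjusted p = 0.168). The antigen presentation genes H2-Aa and H2-Ab1 fell (-1.98 and -1.48), from 4.51 ± 1.31 and 5.06 ± 0.113 scaled CPM, and the integrin gene Itgax rose by 0.63. Of 13 fibroblast markers only 2 were high enough to test, and both rose: Acta2, smooth muscle actin, from 0.537 ± 0.452 to 10.0 ± 1.17 scaled CPM, and Pdgfrb, a growth factor receptor, from 0.298 ± 0.0909 to 1.23 ± 0.217. None of 11 epithelial markers and none of 12 lymphocyte markers in the files reached the level for testing.

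**Figure D2:**
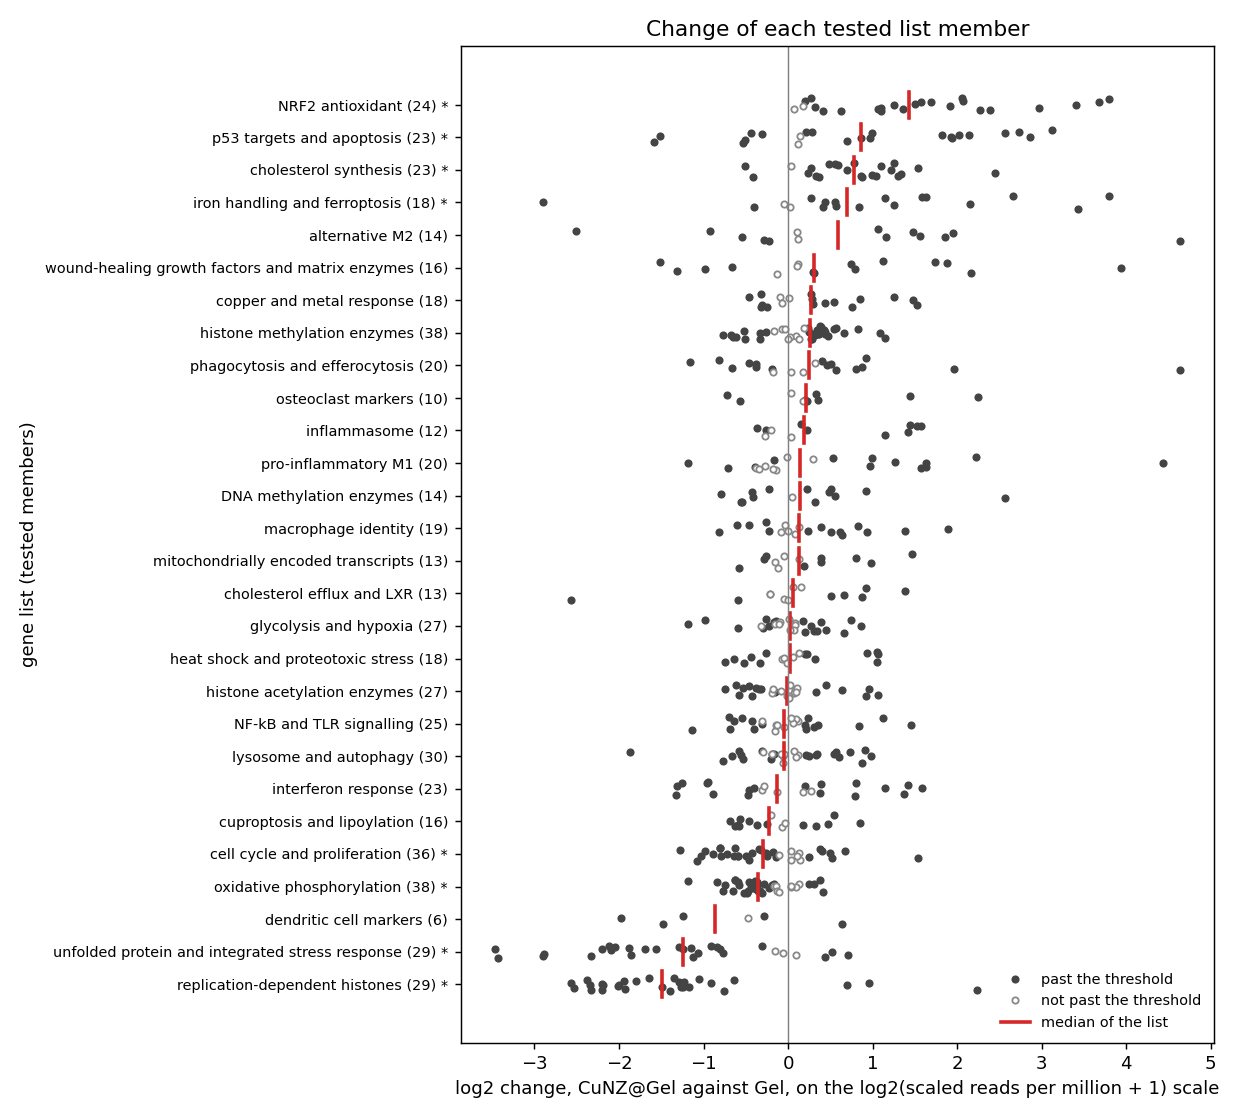
Each point is the log2 change, CuNZ@Gel against Gel on the log2(scaled CPM + 1) scale, of 1 tested member of the gene list named on the vertical axis, filled where it passed the threshold adjusted over all genes. Red lines are list medians, the tested members are in parentheses, and a star marks the 8 lists past camera, whose medians run from -1.50 for histones to 1.43 for NRF2 genes.

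In all, 8 of the 28 lists tested passed camera at an adjusted p under 0.05, 4 as raised and 4 as lowered. With an estimated correlation none of the 28 lists passed, the lowest adjusted p being 0.207. That run has only 2 residual degrees of freedom, so it cannot tell which of the 8 lists hold. The estimated correlation itself was 0.529 for oxidative phosphorylation and at most 0.007 for the others of the 8, against the preset 0.01. The medians of these 8 lists kept their sign under each scaling tried. With libraries scaled by total reads only, the medians of 27 of the 28 lists were higher, by up to 0.24, and 4 changed sign. That of the dendritic cell list was lower by 0.27, with 5 tested members in place of 6. The shift of 0.24 was that of the phagocytosis list, with 19 tested members in place of 20. These shifts therefore also reflect members that left the filter. The length and GC correction moved the medians by -0.33 to 0.36, and 4 changed sign. With total reads only, more genes were raised than lowered in the NF-kB (11 and 6), interferon (10 and 7), heat shock (10 and 5) and lysosome (14 and 6) lists. For all lists other than the 4 for which a count adjusted over the list alone is given, these counts equalled those over all genes. Median and camera direction differed in sign for the NF-kB list, whose mean was -0.02 and median -0.05 with a direction of up, and for the lysosome list, whose median was -0.05 with a direction of up.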

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

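Total reads only, the crossed block and the length and GC correction were chosen after the data were seen. Other scalings, filters, pseudocount and voom weights gave 6926 to 7905 changed genes, and with each library left out 6616 to 6966 changed, where the lone library of a group is assumed to vary like the others. Genes of the naming rule past the threshold stayed past it with any 1 library left out where still tested. They were largely picked by small p in these same libraries, so this is no separate support. Among all called genes, part lost the call with each library left out. Of all called genes, at most 1 changed sign per library left out. The test against a minimum fold of 1.5 called 1955 genes, 1015 raised and 940 lowered, because it asks for a larger change. Of the genes of the naming rule past the main threshold, 21 did not pass this test. The log2 change of Nos2, not past the test, ranged from -0.36 to 0.002 with a library left out, the latter without Gel replicate 2, and the cause was not tested. With the length and GC correction 7266 genes changed, and 6022 of the 6092 shared with the 7770 calls kept their direction. Against 8 lists (4 raised and 4 lowered), an estimated correlation passed 0 lists, with 0 raised and 0 lowered, where camera has 2 residual degrees of freedom, and 5 lists had an unadjusted p under 0.05. Fry, which tests a list alone, passed 17, of which 13 were raised. Those not past camera were the copper, M1, M2, inflammasome, DNA methylation, wound-healing, phagocytosis, macrophage identity, osteoclast and dendritic cell lists. With a library left out 12 to 14 lists passed, 8 to 10 of them raised and 3 to 4 lowered, and with the length and GC correction 11 passed, 8 raised. For both of these the cause was not tested. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.116, across genes, over only 2 pairs. The replicate block called 7489 genes and 13 lists, 9 of them raised, and the cause was not tested. Beyond the 8 lists, the block passed the copper, M1, M2, inflammasome and phagocytosis lists. A crossed pairing as block called 8370 genes. Count tests planned with other packages were not run, because the files held log2 values. Depth limits the genes near 3 reads, which is 0.189 to 0.234 scaled CPM.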

Other observations

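Gene families in this part were chosen after the data were seen, and so were the tests with RNAs that lack a poly(A) tail, with S-phase genes and with chaperones of the endoplasmic reticulum. The genes of the translation machinery fell together in CuNZ@Gel. All 77 genes for cytosolic ribosomal proteins were lowered, with log2 changes from -1.84 to -0.70 and a median of -1.13. Rpl3 fell from 3512 ± 25.8 to 983 ± 46.3 scaled CPM (SD, n = 2 per group) and Rpl10a from 1316 ± 23.9 to 367 ± 7.04. Other genes whose mRNAs start with the same 5′ terminal oligopyrimidine tract, such as Eef1a1 and Npm1 for an elongation factor and nucleophosmin, were lowered in 20 of 20 cases (median -0.95). Of cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 17 of 20 were lowered and 1 was raised (median -0.93). Host genes of small nucleolar RNAs were lowered in 14 of 15 cases (median -1.81), among them Gas5, from 250 ± 4.92 to 70.3 ± 2.38 scaled CPM, and Zfas1, from 154 ± 11.1 to 26.6 ± 3.08. These medians kept their sign under each scaling tried. Camera gave adjusted p from 1.18e-35 to 8.54e-08 for these 4 families, on sets picked because they moved (adjusted p = 0.227 to 0.258 with an estimated correlation).

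Glutathione S-transferase genes, which conjugate glutathione to electrophiles, were raised in 10 of 15 cases and lowered in 3, with a median log2 change of 1.20, or 0.90 with the 5 genes at 0 in both Gel libraries set to the level of 3 reads per library. Gsta3 had 0 reads in Gel and 6.42 ± 0.0145 scaled CPM in CuNZ@Gel, and Mgst2 rose from 22.3 ± 1.35 to 70.8 ± 4.75. Camera gave an adjusted p of 0.00683 (adjusted p = 0.258 with an estimated correlation). Genes with Clec symbols, not all of which encode C-type lectin receptors, were raised in 7 of 14 cases and lowered in 3. They did not pass camera (adjusted p = 0.101). Clec4n, which encodes Dectin-2, had the largest log2 change among them, at 4.05.

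Ribosomal protein genes are short, abundant and prone to share reads with pseudogenes. After correction of each library for transcript length and GC content their median log2 change was -0.85 and 77 of 77 remained lowered, which argues against that trend as the whole cause. Random lists matched on level and transcript length had a median of -0.25, and the lowest of 10000 was -0.59, above the ribosomal median. The family was picked because it moved, so its place below these lists says only that the matched genes fell less. The summed level of 23 ribosomal pseudogenes in CuNZ@Gel was 0.437 times that in Gel, the opposite of a shift of reads towards them. An effect of CuNZ stays open, and no biological explanation was tested.

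Replication-dependent histone genes had a median log2 change of -1.50, and -1.14 after correction for transcript length and GC content, which argues against that trend as the whole cause. Lower recovery of RNA without a poly(A) tail may contribute, since non-histone RNAs of this kind had a median of -1.54, or -0.58 after the same correction. With that correction 5 of these 7 RNAs were lowered, against 7 without it. Rn7s1 and Rn7s2 among them share reads and are uncertain. Fewer cells in S phase stays open: polyadenylated S-phase genes had a median of -0.22 ± 0.40 (SD over 20 genes), lowered in 12 cases and raised in 4 (median -0.04, with 6 lowered and 5 raised, with total reads only), between the values that the tests had set for and against it. An effect of CuNZ on histone transcription was not separated from these.

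The gene of the transcription factor ATF4 and genes it induces were lowered in 17 of 17 tested cases, with a median log2 change of -2.05. Aars, Gars and Wars1 among them were also counted in the synthetase family above, so these families are not separate. After correction for transcript length and GC content the median of the 16 ATF4-type genes with a transcript was -1.79, which argues against that trend. Less stress in the endoplasmic reticulum stays open: its chaperones, taken from the same list after their values were seen, had a median of 0.27 ± 0.35 (SD over 6 genes), with 3 raised and none lowered, whereas Xbp1 and Herpud1, other genes of that stress, fell (-0.77 and -1.69). An effect of CuNZ stays open, as untested, and untreated cells were not analysed here, so whether the Gel or the CuNZ@Gel level was the unusual one was not decided.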
